A study of Homo sapiens with 6 samples.

How the data were processed

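The data are read counts per gene symbol for 6 RNA sequencing libraries of A549 cells, 3 given PBS and 3 given rhTR11B, grouped by the treatment in the labels. Total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 kit, per the labels' protocols, which do not state a strand setting. The authors' deposited count table and FPKM table were made with fastp, HISAT, HTSeq, R 3.2.0 and DESeq2 on genome build GRCh38, per the submitters' processing notes. Which tool did which step, the other versions, the annotation and the strand setting of the counting are not given in the sources used here. Without strand, reads of overlapping genes on opposite strands cannot be told apart. The deposited FPKM values equal count divided by a gene length and by the library's total for 100% of values within a relative tolerance of 0.001, so both tables hold the same measurements. Of 19876 symbols, 18832 matched a RefSeq table of GRCh38.p14, from which gene types and coordinates were taken; some symbols are older names. In this table mitochondrially encoded genes carry names without a prefix, such as COX2 and ND5.

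From the deposited counts, edgeR 4.0.16 in R 4.3.3 was used for the comparison: genes kept by filterByExpr (minimum count 10), TMM scaling, a design with the group as the only term, and the quasi-likelihood test with Benjamini-Hochberg adjustment over the 13567 genes kept. CPM values are those of the cpm function of edgeR on the TMM-scaled library sizes. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The common biological coefficient of variation was 0.0656. Library totals of 36315751 to 38148838 counts leave little counting error for most genes, and the spread between libraries sets the precision. Pairs of libraries within a group differed by 5.13 to 24.7 times the chi-square per degree of freedom that sampling noise gives, so no pair was treated as the same library. On counts simulated from these libraries' means and sizes, with 200 changed genes and 13454 genes run, the edgeR step recovered 71.6% of 67 genes changed 1.3-fold, 95.5% of 67 changed 1.5-fold and 100% of 66 changed 2-fold, with 13 false calls among 191. The simulation drew each gene independently and held no library that deviated as a whole. Its rates may therefore not hold for the real libraries.

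Gene lists, 29 in all with 527 genes of which 487 were found in the table, were tested with camera (limma 3.58.1, preset correlation 0.01), with camera and an estimated correlation, and with fry, adjusted over the 27 lists with at least 3 tested members. They cover ligands and partners of osteoprotegerin, signalling targets, cell cycle, metabolism, stress responses, epithelial, mesenchymal and lung genes, ribosomal and mitochondrial genes, and markers of fibroblasts, endothelial and blood cells. Older symbols of histone genes already listed under their present ones were dropped once the table had been seen. The lists, the test, its design, the alternatives except those named as added, and the rule for named genes were fixed before the data were examined. The rule takes TNFRSF11B, TNFSF11, TNFSF10 and TNFRSF11A, then up to 10 increases and 10 decreases with the largest log2 fold change among genes with an adjusted p under 0.05, a mean of at least 2 CPM and no overlap between the groups, then up to 4 members of each list with the smallest p, and for the closing part up to 20 further called genes with the smallest p. Other list members named beside these were chosen after their values were seen. Some genes that the rule takes are not reported by name.

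Alternatives were DESeq2 size factors or library size alone in place of TMM, the Wald test of DESeq2 1.42.0, limma-voom, no low-count filter or a mean of at least 5 CPM, the replicate number as a block, other thresholds, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 1 or with no filter, and leaving out each library. Added after the data were seen were per-library offsets for GC content (from GENCODE 29 transcripts) and length, the same genes without offsets, and a fit without the 13 mitochondrially encoded genes. Shares of counts were compared with exact permutation tests. Families by gene symbol in the closing part were drawn up after the called genes, and exploratory trends of fold change with GC content and length, had been seen.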

Results

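Gene expression was measured by RNA sequencing in A549, an established line of human lung adenocarcinoma cells, cultured with rhTR11B or, as the negative control, with phosphate-buffered saline (PBS). TR11B is a short name of TNFRSF11B (osteoprotegerin), a secreted decoy receptor that binds TNFSF11 (RANKL) and TNFSF10 (TRAIL). The labels do not spell out rhTR11B, and they give no dose and no time of treatment. Each group held 3 libraries, called biological replicates in the labels. Whether they came from separate cultures is not stated, so the p-values measure the spread between these libraries, which may be technical. The deposited table held read counts for 19876 gene symbols. The totals were 37203313, 38016879 and 38148838 counts in PBS replicates 1, 2 and 3 and 36731663, 36992958 and 36315751 counts in rhTR11B replicates 1, 2 and 3. The comparison asked which transcripts of A549 cells differ when TR11B is supplied from outside the cells.

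In A549 cells given rhTR11B, genes of mesenchymal cells and invasion, of antigen presentation and of the NF-kB response stood higher as groups, and heat shock and cytosolic ribosomal protein genes stood lower. Against all other tested genes, camera with a preset correlation gave these 5 lists adjusted p = 5.15e-08, 2.52e-09, 1.11e-06, 2.52e-09 and 1.49e-21 in that order, and adjusted p = 0.376, 0.301, 0.376, 0.159 and 0.376 with an estimated correlation. The groups' median log2 fold changes were 0.36 for the mesenchymal and invasion list, 0.33 for antigen presentation, 0.23 for NF-kB targets, -0.25 for heat shock and -0.21 for cytosolic ribosomal proteins. Among the genes that rose, the surface protease MMP14 reached 1.33-fold and the adhesion molecule ICAM1 1.37-fold its PBS level. Complement component C3 rose 1.72-fold, from 113 ± 13.9 to 195 ± 34.6 CPM (SD, n = 3 per group). Among those that fell, the constitutive chaperone HSPA8 went from 2031 ± 24.8 to 1657 ± 33.4 CPM and the inhibitor of differentiation ID2 from 9.71 ± 0.290 to 6.79 ± 0.872 CPM. The same rhTR11B libraries had a higher mitochondrial and a lower ribosomal protein share of counts. The membrane protein families TMEM and SLC without SLC25, chosen after the calls were seen, had medians of 0.14 and 0.18. The 41 SLC25 genes had -0.05. The called members of the higher lists that are named below mostly encode membrane or secreted proteins too, MMP14, ICAM1 and HLA-B among them. Of the members named as not passing, VIM, ZEB1, SNAI1, NFKBIA, TNFAIP3, PSMB8 and PSMB9 encode neither, while IL6 is secreted. Whether the lists moved apart from this difference between membrane and other transcripts was not tested.

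**Figure D1:**
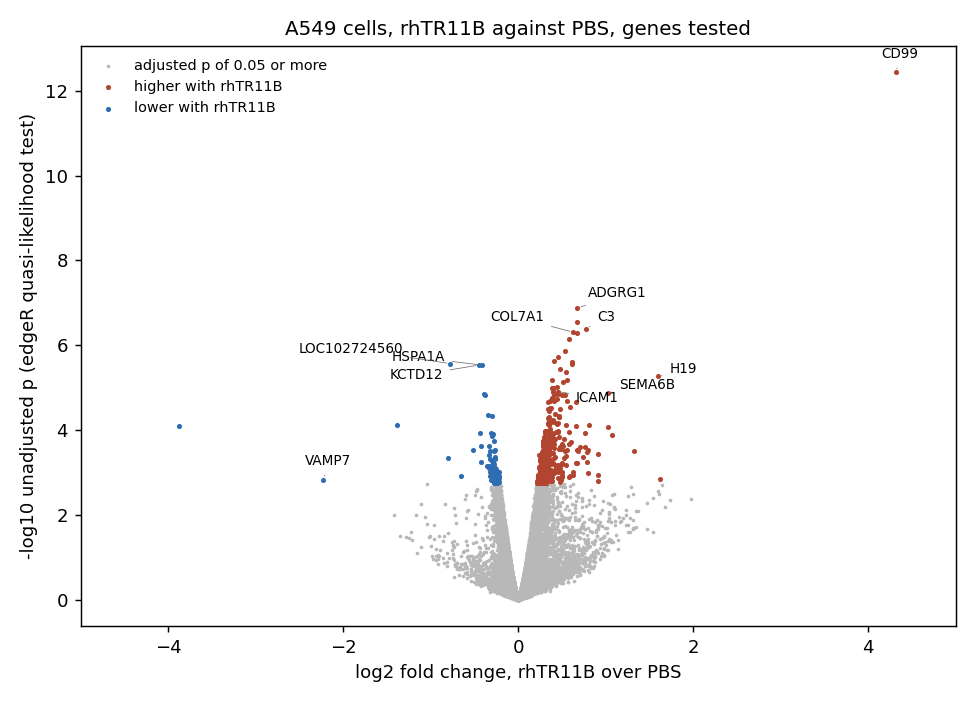
Each point is a tested gene; the x axis is the log2 fold change of rhTR11B over PBS (3 libraries each) and the y axis is −log10 of the unadjusted p of edgeR's quasi-likelihood test. Red points are the 396 genes higher and blue points the 92 genes lower at an adjusted p under 0.05, and CD99 lies apart at a log2 fold change of 4.32.

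Of 13567 genes tested with edgeR's quasi-likelihood test, 396 were higher and 92 lower with rhTR11B at a Benjamini-Hochberg adjusted p under 0.05. Higher genes made up 81.1% of the calls. The median length behind the FPKM values was 4708.5 bases for higher and 2261 for lower genes, against 3981 for all tested genes. Offsets for GC content and length, added after the data were seen, cover genes with a GC value. There 372 of the higher and 60 of the lower calls passed with offsets, and 377 and 68 without. The changes were small. The median log2 fold change was 0.33 among the higher and -0.28 among the lower genes. In all, 38 increases and 6 decreases reached 1.5-fold, and 7 increases and 3 decreases reached 2-fold. The 3 rhTR11B libraries lay wholly above or below the 3 PBS libraries for 485 of the 488 called genes and for 29.1% of all tested genes, where chance gives 10% on average. Because genes vary together, the share in a single split can lie far from 10%, and it was not computed for other splits. Of 27 lists fixed beforehand with at least 3 tested members, camera with a preset correlation called 11, 7 of them up and 4 down. With an estimated correlation camera called 0, with 3 lists at an unadjusted p under 0.05, and fry called 1, heat shock. The estimated correlation was 0.92 for cytosolic ribosomal proteins, 0.75 for mitochondrially encoded genes and 0.71 for osteoprotegerin partners. It was 0.26 for NF-kB targets and 0.06 for heat shock. List tests with 1 library left out, given below, used only the preset 0.01 and do not allow for such correlation. Another split of the same 6 libraries, PBS replicate 1 with rhTR11B replicates 1 and 3 against the other 3, gave 12 lists with the preset correlation. Fewer genes passed with a control library left out: 18 were higher and 5 lower without PBS replicate 2, and 9 higher and 3 lower without PBS replicate 3, with 2258 and 2424 genes at an unadjusted p under 0.05 against 3279 with all libraries. There were 255 and 27 without PBS replicate 1, 903 and 427 without rhTR11B replicate 1, 385 and 47 without rhTR11B replicate 2, and 295 and 86 without rhTR11B replicate 3. In each of the 6 fits all 488 called genes kept their direction, and the median size of their log2 fold change was 0.25 to 0.36, against 0.32 with all libraries, though they were picked from these same libraries. For the 485 without overlap, leaving out 1 library could hardly turn the direction, so the kept direction says little about stability. Of the 79 called genes taken by the rule for named genes, 11 passed in each of these 6 fits, among them CD99, LOC102724560, KCTD12, ADGRG1, SECTM1, C3, COL7A1, PODXL, NPNT and TBC1D8. The other 68 did not pass without PBS replicate 3.

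The libraries of the groups also differed in composition. The 13 mitochondrially encoded genes took 7.71%, 6.63% and 7.31% of the counts in PBS replicates 1 to 3 and 8.75%, 7.88% and 10.4% in rhTR11B replicates 1 to 3 (n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). The 78 genes of cytosolic ribosomal proteins took 4.71% ± 0.0699 of the counts with PBS and 4.01% ± 0.379 with rhTR11B (exact permutation p = 0.1), with 3.58% in rhTR11B replicate 3. On the first principal component of the log2 CPM values, which held 36.4% of the variance, rhTR11B replicate 3 stood at 25.7. The other rhTR11B libraries stood at 2.66 and 8.63, and the PBS libraries at -5.96, -18.4 and -12.7.

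TNFRSF11B itself (chromosome 8, 118923557 to 118951885 on GRCh38.p14) was detected in every library, with 289, 217 and 202 counts with PBS and 270, 230 and 269 with rhTR11B. Its level of 6.22 ± 1.31 CPM with PBS and 7.04 ± 0.761 CPM with rhTR11B did not pass the test (log2 fold change 0.18, SE 0.15, adjusted p = 0.479). With 1 library left out its log2 fold change ran from 0.08 without PBS replicate 3 to 0.36 without PBS replicate 1. TNFRSF11A (RANK, the receptor of TNFSF11; chromosome 18, 62325310 to 62391288) had 4.40 ± 0.428 CPM with PBS and 4.39 ± 0.331 CPM with rhTR11B (log2 fold change -0.00, SE 0.15, adjusted p = 0.995). TNFSF10 had 2, 0 and 2 counts with PBS and 1, 2 and 0 with rhTR11B and was too low to test. TNFSF11 was not analysed here. Of 9 tested ligands and partners of osteoprotegerin, 5 rose (camera adjusted p = 7.23e-06, adjusted p = 0.376 with an estimated correlation), or 7 when adjusted over the list alone. The 5 were the heparan sulfate proteoglycans SDC1 (log2 fold change 0.35, adjusted p = 0.0180), GPC1 (0.34, 0.0370) and SDC4 (0.23, 0.0497) and the integrin chains ITGAV, from 888 ± 47.4 to 1083 ± 63.6 CPM, and ITGB3, from 45.3 ± 1.23 to 56.5 ± 5.19 CPM. Without PBS replicate 2 the adjusted p of these 5 genes ran from 0.145 to 0.217, and without PBS replicate 3 from 0.130 to 0.194. Without PBS replicate 1 and without rhTR11B replicate 3, 3 of the 5 passed (adjusted p from 0.0442 to 0.0913 and from 0.00601 to 0.0659). Their median log2 fold change was 0.30 and 0.32 without PBS replicates 2 and 3, against 0.32 with all libraries. Without rhTR11B replicate 3 it was 0.24. The list was called by camera with the preset correlation in all 6 fits (adjusted p up to 6.53e-05). All 5 called genes encode cell-surface proteins. Among membrane protein families, chosen after the calls were seen, the median was 0.23 for 22 integrin chains, which include ITGAV and ITGB3. It was 0.14 for TMEM genes and 0.18 for SLC genes outside SLC25, but -0.05 for SLC25 and -0.07 for SMIM genes. Whether the partners moved apart from other membrane proteins was not tested.

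Among 16 tested mesenchymal and invasion genes, 7 rose and 9 did not pass (camera adjusted p = 5.15e-08, adjusted p = 0.376 with an estimated correlation). When adjusted over the list alone, 10 rose. MMP14, a membrane-bound metalloproteinase, went from 115 ± 4.34 to 152 ± 8.74 CPM (log2 fold change 0.41, SE 0.06, adjusted p = 0.00264), and CDH2 (N-cadherin) from 117 ± 6.42 to 154 ± 12.1 CPM (adjusted p = 0.00556). The urokinase gene PLAU rose by 0.38 (adjusted p = 0.0196) and its receptor PLAUR by 0.41 (adjusted p = 0.0239). The matrix protein FN1 rose by 0.78 (SE 0.18, adjusted p = 0.0257), the fibronectin receptor chain ITGA5 by 0.36 (adjusted p = 0.0145) and the collagen cross-linking enzyme LOXL2 by 0.30 (adjusted p = 0.0329). The intermediate filament gene VIM (-0.03, adjusted p = 0.814) and the transcription factors ZEB1 (-0.06, 0.676) and SNAI1 (-0.08, 0.702) did not pass. Of the 7 calls, 6 held without PBS replicate 1 (adjusted p up to 0.0608), 6 without rhTR11B replicate 3 (up to 0.0562) and 1 without PBS replicate 2 (up to 0.195). Without PBS replicate 3 their adjusted p ran from 0.0641 to 0.168. Their median log2 fold change was 0.36 and 0.39 without PBS replicates 2 and 3, against 0.40 with all libraries. It was 0.32 without rhTR11B replicate 3. Camera with the preset correlation called the list in all 6 fits (adjusted p up to 9.60e-06). In the same libraries the mitochondrial share of counts was higher and the ribosomal protein share lower with rhTR11B.

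**Figure D2:**
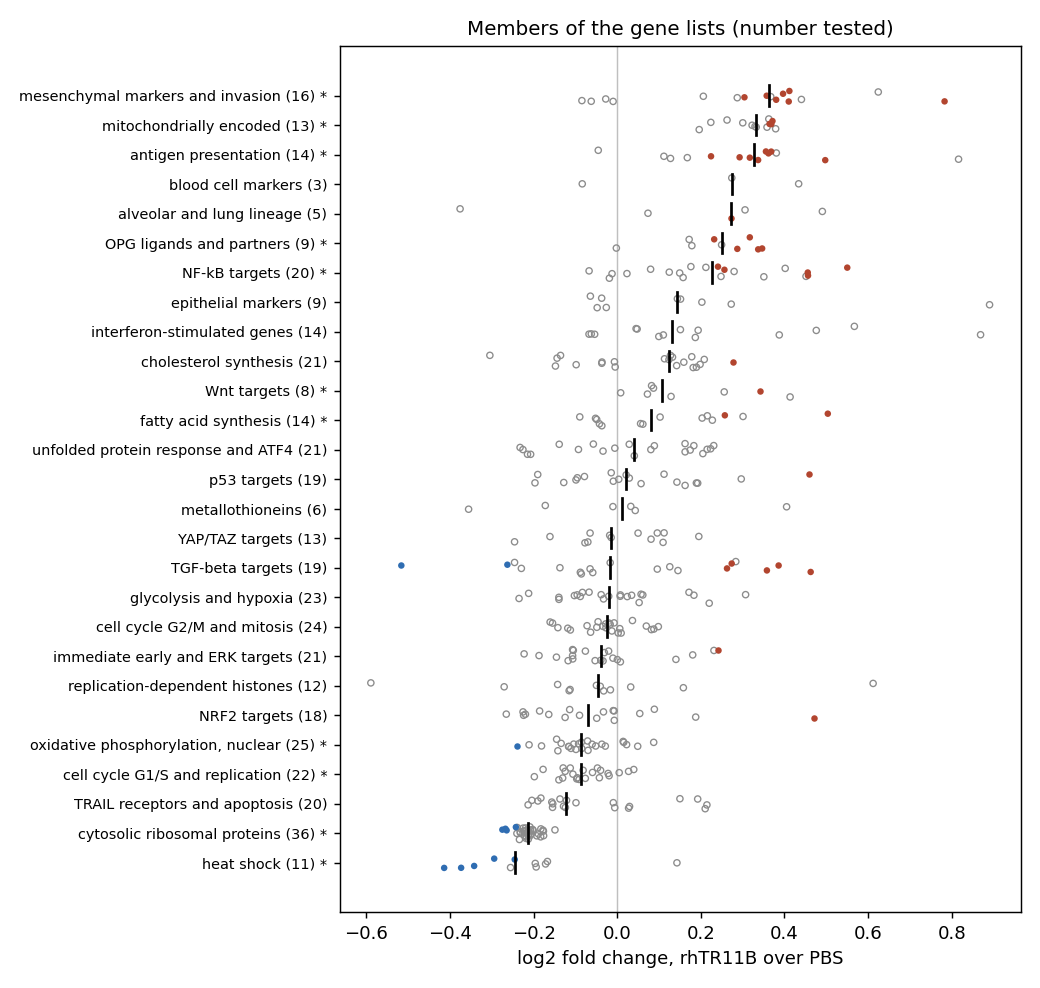
Log2 fold change of rhTR11B over PBS (x axis) for each tested member of the 27 lists with at least 3 tested members (number in brackets); black bars are medians, red and blue points are members higher and lower at an adjusted p under 0.05, open points did not pass, and an asterisk marks a camera adjusted p under 0.05 with the preset correlation. Medians run from -0.25 for heat shock to 0.36 for mesenchymal markers and invasion.

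Of 20 tested NF-kB targets, 5 rose, or 10 when adjusted over the list alone (camera adjusted p = 1.11e-06, adjusted p = 0.376 with an estimated correlation). ICAM1 (chromosome 19, 10271120 to 10286615), a leukocyte adhesion molecule, went from 446 ± 30.9 to 612 ± 72.1 CPM (log2 fold change 0.46, SE 0.08, adjusted p = 0.00561), and the monocyte chemokine CCL2 from 184 ± 17.4 to 253 ± 26.1 CPM (adjusted p = 0.00561). The cytokine genes LTB and TNF rose by 0.55 (adjusted p = 0.0145) and 0.26 (adjusted p = 0.0474), and TNFAIP2 by 0.24 (adjusted p = 0.0492). The pathway's own feedback genes NFKBIA (0.02, adjusted p = 0.848) and TNFAIP3 (0.18, 0.0917) and the cytokine IL6 (0.35, 0.0663) did not pass. Without PBS replicate 2 the adjusted p of the 5 called members ran from 0.0717 to 0.248, and without PBS replicate 3 from 0.110 to 0.197. Of the 5, 3 passed without rhTR11B replicate 2 (adjusted p up to 0.0913), and 4 each without PBS replicate 1 and rhTR11B replicate 3 (up to 0.0502 and 0.0620). The median log2 fold change of the 5 was 0.41 and 0.42 without PBS replicates 2 and 3, against 0.46 with all libraries. It was 0.36 without rhTR11B replicate 3. Camera with the preset correlation called the list in all 6 fits (adjusted p up to 3.68e-05).

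Of 14 tested antigen presentation genes, 8 rose, or 9 when adjusted over the list alone (camera adjusted p = 2.52e-09, adjusted p = 0.301 with an estimated correlation). The class I heavy chain HLA-B (chromosome 6, 31353875 to 31357179) went from 30.0 ± 3.33 to 42.3 ± 3.90 CPM (log2 fold change 0.50, SE 0.09, adjusted p = 0.00561), HLA-E from 215 ± 13.4 to 278 ± 17.8 CPM (adjusted p = 0.00671) and the light chain B2M from 372 ± 18.8 to 476 ± 41.0 CPM (adjusted p = 0.0119). HLA-C, the peptide transporter genes TAP1 and TAP2 and the loading factor TAPBP rose by 0.36, 0.29, 0.22 and 0.32. The immunoproteasome subunits PSMB8 (0.11, adjusted p = 0.406) and PSMB9 (0.17, 0.243) did not pass. Class I genes resemble each other, so reads may be split among them. Without PBS replicate 2 the adjusted p of the 8 called members ran from 0.0717 to 0.195, and without PBS replicate 3 from 0.115 to 0.182. Of the 8, 7 passed without PBS replicate 1 (up to 0.0897) and 7 without rhTR11B replicate 2 (up to 0.0687). Their median log2 fold change was 0.28 and 0.34 without PBS replicates 2 and 3, against 0.35 with all libraries. It was 0.26 without rhTR11B replicate 3. Camera with the preset correlation called the list in all 6 fits (adjusted p up to 1.23e-07).

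In 14 tested interferon-stimulated genes edgeR called 0, with 2 at an unadjusted p under 0.05, and DESeq2 called 1 higher, and 1 rose when adjusted over the list alone. The values nearest to passing were IFI6 at 0.48 (adjusted p = 0.0586, and 0.0364 with GC and length offsets) and IFIT3 at 0.39 (adjusted p = 0.188). The list's median was 0.13 (camera adjusted p = 0.0975, adjusted p = 0.376 with an estimated correlation; adjusted p = 0.0459 without rhTR11B replicate 3). With 1 library left out it had a median from 0.06 without rhTR11B replicate 2 to 0.15 without rhTR11B replicate 1. Of 20 TRAIL receptor and apoptosis genes edgeR called 0, with 9 at an unadjusted p under 0.05, and DESeq2 called 1 lower. When adjusted over the list alone 3 rose and 3 fell. Their median was -0.12 (camera adjusted p = 0.117, adjusted p = 0.376 with an estimated correlation). The survival gene MCL1 stood at -0.20 (adjusted p = 0.0603), the pore-forming BAK1 at -0.21 (0.0880), the caspase inhibitor XIAP at -0.18 (0.0926) and the TRAIL receptor TNFRSF10B at 0.19 (0.0880). The apoptosis list had a median from -0.14 without rhTR11B replicate 2 to -0.06 without rhTR11B replicate 3 with 1 library left out. Without rhTR11B replicate 1 IFI6, BAK1 and TNFRSF10B passed (adjusted p = 0.0180, 0.0448 and 0.0449), and without rhTR11B replicate 3 BAK1 and TNFRSF10B had -0.14 and 0.13.

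All 5 called members of the 11 tested heat shock genes fell, or 10 when adjusted over the list alone (camera adjusted p = 2.52e-09, adjusted p = 0.159 with an estimated correlation; fry adjusted p = 0.0168). HSPA8 (chromosome 11, 123057489 to 123062462) decreased from 2031 ± 24.8 to 1657 ± 33.4 CPM (log2 fold change -0.29, SE 0.06, adjusted p = 0.0195). The inducible HSP70 genes HSPA1A and HSPA1B fell, from 91.4 ± 5.82 to 68.6 ± 1.76 CPM and from 65.9 ± 4.03 to 52.0 ± 1.41 CPM (adjusted p = 0.00264 and 0.0113). As near-identical copies they may exchange reads. The co-chaperone DNAJB1 fell, from 85.3 ± 3.37 to 65.8 ± 4.34 CPM (adjusted p = 0.00561), as did the mitochondrial chaperone HSPD1 (log2 fold change -0.25, adjusted p = 0.0473). The small heat shock gene HSPB1 had 0.14 (adjusted p = 0.219). Without PBS replicate 2 the adjusted p of the 5 called members ran from 0.0134 to 0.224, and without PBS replicate 3 from 0.0572 to 0.187. Of the 5, 1 passed without PBS replicate 2, and 4 each without PBS replicate 1 and rhTR11B replicate 2 (up to 0.0649 and 0.121). Their median decrease, in log2 units, was 0.37 and 0.37 without PBS replicates 2 and 3, against 0.34 with all libraries. It was 0.30 without PBS replicate 1 and 0.32 without rhTR11B replicate 3. Camera with the preset correlation called the list in all 6 fits (adjusted p up to 7.25e-07).

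The 36 tested genes of cytosolic ribosomal proteins all had negative log2 fold changes, with a median of -0.21. Over all genes 4 fell, and 36 when adjusted over the list alone (camera adjusted p = 1.49e-21, adjusted p = 0.376 with an estimated correlation). RPS23 and RPS14 fell, from 528 ± 19.5 to 437 ± 50.2 CPM and from 699.7 ± 27.4 to 581 ± 54.6 CPM (adjusted p = 0.0472 and 0.0435), as did RPL35 (log2 fold change -0.26, adjusted p = 0.0387) and RPL7A (-0.24, 0.0496). Without PBS replicate 1, 2 or 3 the adjusted p of these 4 genes ran from 0.0637 to 0.0919, from 0.165 to 0.209 and from 0.188 to 0.201, respectively, and 1 passed without rhTR11B replicate 2 (up to 0.0680). The median decrease of the 4, in log2 units, was 0.25 and 0.25 without PBS replicates 2 and 3, against 0.27 with all libraries. It was 0.19 without rhTR11B replicate 3, where the list median was -0.15. Camera with the preset correlation called the list in all 6 fits (adjusted p up to 8.20e-17). With offsets for GC content and transcript length, added after the data were seen, the list median was -0.14 (camera adjusted p = 1.05e-11), and RPL35 and RPL7A did not pass (adjusted p = 0.0548 and 0.0879). Nuclear genes of oxidative phosphorylation had a median of -0.09 (camera adjusted p = 0.00221, adjusted p = 0.376 with an estimated correlation). The complex III subunit UQCRH fell, from 165 ± 2.17 to 139 ± 11.9 CPM (adjusted p = 0.0468), as the only 1 of 25, and 1 fell when adjusted over the list alone. With the same offsets the median of that list was 0.00, its camera adjusted p 0.700 and the adjusted p of UQCRH 0.145, where the same genes without offsets gave 0.0510. The adjusted p of UQCRH was 0.0963, 0.194 and 0.179 without PBS replicates 1, 2 and 3, and 0.0712 and 0.0577 without rhTR11B replicates 2 and 3.

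The 13 mitochondrially encoded genes, subunits of the respiratory chain and ATP synthase, had positive log2 fold changes with a median of 0.33. Over all genes 3 rose, and 11 when adjusted over the list alone (camera adjusted p = 3.28e-09, adjusted p = 0.376 with an estimated correlation). The called members were the cytochrome c oxidase subunit COX2 (not the prostaglandin synthase of the same abbreviation), from 7146 ± 490.4 to 9227 ± 1375 CPM (log2 fold change 0.37, SE 0.09, adjusted p = 0.0400), CYTB (0.37, 0.0472) and ATP6 (0.36, 0.0478). ND5 had 0.38 (adjusted p = 0.0516). The adjusted p of the 3 called genes ran from 0.222 to 0.244 without PBS replicate 2 and from 0.182 to 0.191 without PBS replicate 3, and 1 passed without PBS replicate 1 (up to 0.0573). Their median log2 fold change was 0.30 and 0.38 without PBS replicates 2 and 3, against 0.37 with all libraries, and 0.25 without rhTR11B replicate 3. The list median was 0.22 without that library, and camera with the preset correlation called the list in all 6 fits (adjusted p up to 4.02e-06). ND5 passed in the fits without rhTR11B replicates 1, 2 and 3 (adjusted p = 0.0243, 0.0216 and 0.0423). This rise is the mitochondrial share of counts seen gene by gene, and it was largest in rhTR11B replicate 3, where the share was 10.4%.

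**Figure D3:**
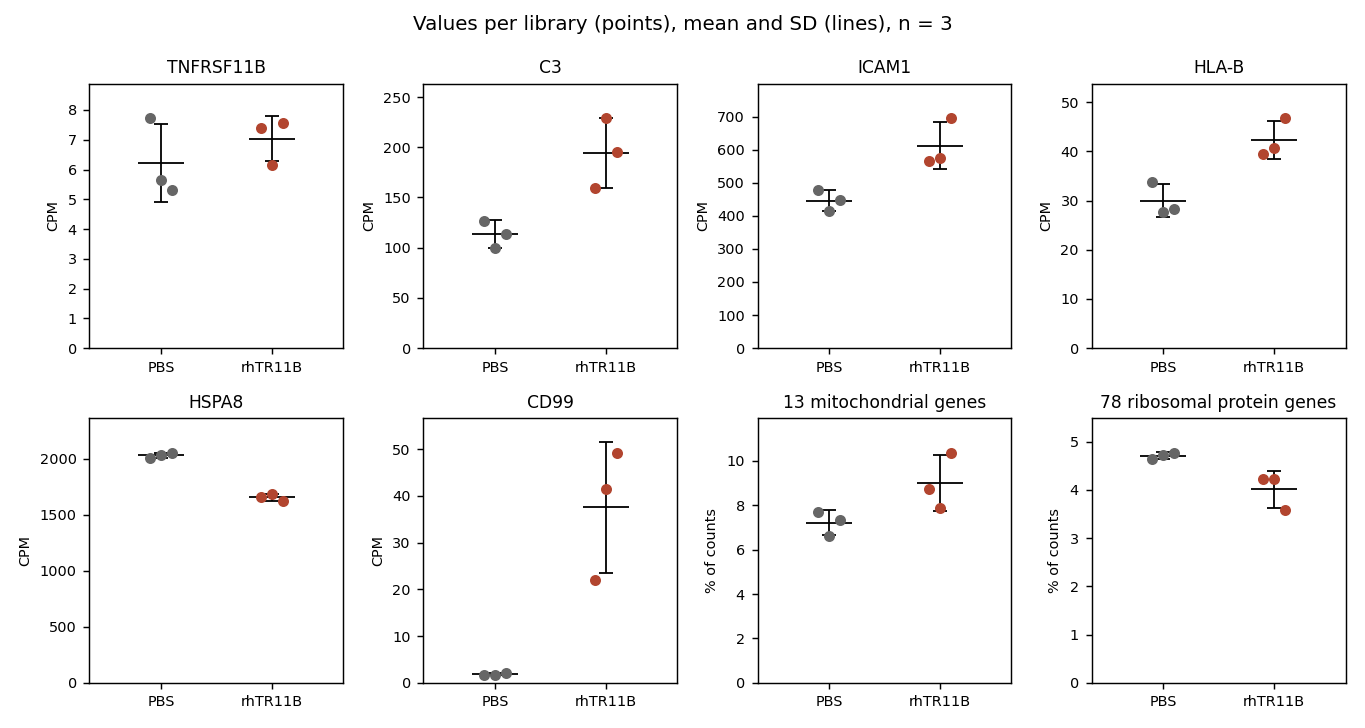
Values of single libraries (points) with mean and SD (lines, n = 3 per group): normalised counts (CPM) for 6 genes, and percent of all counts for the mitochondrially encoded and the ribosomal protein genes, each y axis starting at 0. The rhTR11B libraries lay above the PBS libraries for C3, ICAM1, HLA-B, CD99 and the mitochondrial share, below them for HSPA8 and the ribosomal protein share, and overlapped them for TNFRSF11B.

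Among 19 tested TGF-beta targets, 5 rose and 2 fell, or 6 and 4 when adjusted over the list alone. The latent TGF-beta binding protein gene LTBP2 (0.46, adjusted p = 0.0119), the activin subunit gene INHBA (0.36, 0.0134), the SMAD inhibitor gene PMEPA1 (0.39, 0.0231) and the basement membrane collagens COL4A1 (0.27, 0.0277) and COL4A2 (0.26, 0.0472) rose. ID2 (-0.52, adjusted p = 0.0249) and ID3 (-0.26, 0.0429), which inhibit basic helix-loop-helix transcription factors, fell. Camera, which looks for a shift in 1 direction and may miss members that move both ways, did not call the list. Its camera adjusted p was 0.284, and adjusted p = 0.667 with an estimated correlation. The list had a median of -0.02 but a mean of 0.04 and a test in the upward direction. Of the 7 calls, 3 held without PBS replicate 1 (adjusted p up to 0.0766), 5 without rhTR11B replicate 2 (up to 0.0748) and 6 without rhTR11B replicate 3 (up to 0.0556). Without PBS replicates 2 and 3 their adjusted p ran from 0.0524 to 0.223 and from 0.130 to 0.203, and the median size of their log2 fold change was 0.33 and 0.30 without PBS replicates 2 and 3, against 0.36 with all libraries. The whole list had a median from -0.02 without PBS replicate 1 to 0.07 without rhTR11B replicate 2.

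Of 8 tested Wnt targets, 1 rose, the hyaluronan receptor gene CD44, from 667 ± 18.8 to 846 ± 74.0 CPM (adjusted p = 0.0145; 0.115 and 0.145 without PBS replicates 2 and 3). Adjusted over the list alone, 2 rose. The feedback genes NOTUM (0.26, adjusted p = 0.0580) and AXIN2 (0.41, 0.203) did not pass. NOTUM passed without rhTR11B replicate 1 or 2 (adjusted p = 0.0364 and 0.0449), and AXIN2 had 0.63 without PBS replicate 2. The list's median was 0.11 (camera adjusted p = 0.0301, adjusted p = 0.376 with an estimated correlation). Its camera adjusted p was 0.0714 without PBS replicate 1, 0.0698 without rhTR11B replicate 1 and 0.0630 with GC and length offsets. With 1 library left out the list had a median from 0.11 without PBS replicate 2 to 0.20 without PBS replicate 3. Of 21 immediate early and ERK targets, 1 rose, both over all genes and adjusted over the list alone: IER3, from 249.6 ± 16.1 to 295 ± 18.5 CPM (adjusted p = 0.0474). Its adjusted p was 0.0588, 0.226 and 0.186 without PBS replicates 1, 2 and 3, and 0.132 without rhTR11B replicate 2. The list's median was -0.04 (camera adjusted p = 0.266, adjusted p = 0.579 with an estimated correlation; median from -0.08 without PBS replicate 2 to -0.03 without PBS replicate 1). Among 13 YAP/TAZ targets edgeR, also when adjusted over the list alone, and DESeq2 called 0, with 2 at an unadjusted p under 0.05. AJUBA had -0.16 and CCN2 -0.25 (adjusted p = 0.113 and 0.137), and the list's median was -0.01 (camera adjusted p = 0.716, adjusted p = 0.829 with an estimated correlation). Without rhTR11B replicate 3 CCN2 passed, at -0.38 (adjusted p = 0.0104), and without rhTR11B replicate 1 it had -0.13. The YAP/TAZ list had a median from -0.05 without PBS replicate 1 to 0.01 without PBS replicate 3. Of 19 p53 targets, 1 rose, the death receptor gene FAS, from 23.0 ± 2.13 to 31.6 ± 3.48 CPM (adjusted p = 0.0138; 0.144 without PBS replicate 3), or 2 when adjusted over the list alone. CDKN1A had 0.03 (adjusted p = 0.809) and MDM2 -0.08 (0.471). The p53 list had a median of 0.02 (camera adjusted p = 0.612, adjusted p = 0.682 with an estimated correlation) and, with 1 library left out, a median from -0.01 without rhTR11B replicate 1 to 0.05 without PBS replicate 3.

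Among 22 genes of G1/S and replication edgeR called 0, with 4 at an unadjusted p under 0.05, and DESeq2 called 1 lower, and 0 passed when adjusted over the list alone. The ribonucleotide reductase gene RRM2 stood at -0.20 (adjusted p = 0.0732) and the replication factor genes GINS2 and MCM6 at -0.18 (0.135) and -0.13 (0.193). As a group the list lay lower, with a median of -0.09 (camera adjusted p = 0.00513, adjusted p = 0.575 with an estimated correlation), which was -0.05 without rhTR11B replicate 3. RRM2 passed without rhTR11B replicate 1 (adjusted p = 0.0357). Among 24 genes of G2/M and mitosis edgeR, also when adjusted over the list alone, and DESeq2 called 0, with 4 at an unadjusted p under 0.05. CCNA2 stood at -0.16 and the proliferation marker MKI67 at 0.07 (adjusted p = 0.138 and 0.513), and the list median was -0.02 (camera adjusted p = 0.266, adjusted p = 0.682 with an estimated correlation). With 1 library left out the G2/M list had a median from -0.04 without rhTR11B replicate 1 to -0.02 without PBS replicate 2. Of 12 replication-dependent histone genes edgeR, also when adjusted over the list alone, and DESeq2 called 0, with 1 at an unadjusted p under 0.05. H2BC4 had -0.59 (adjusted p = 0.0857), and the median was -0.05 (camera adjusted p = 0.284, adjusted p = 0.667 with an estimated correlation). Without rhTR11B replicate 1 H2BC4 passed, at -0.86 (adjusted p = 0.0135), and the histone list had a median from -0.14 without PBS replicate 1 to 0.01 without rhTR11B replicate 1.

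In lipid metabolism, 2 of 14 fatty acid synthesis genes rose, the desaturase gene SCD, from 307 ± 13.5 to 367 ± 20.3 CPM, and the triglyceride synthesis gene DGAT2, from 6.67 ± 0.338 to 9.46 ± 1.69 CPM (adjusted p = 0.0324 and 0.0400). It was 5 when adjusted over the list alone. The fatty acid synthase gene FASN had -0.04 (adjusted p = 0.701). The list's median was 0.08 (camera adjusted p = 0.0366, adjusted p = 0.376 with an estimated correlation). Without PBS replicate 3 its median was 0.05 and its camera adjusted p 0.0980. That adjusted p was 0.0624 without rhTR11B replicate 3 and 0.106 with GC and length offsets. Of 21 cholesterol synthesis genes, 1 rose, DHCR7, 1.21-fold (adjusted p = 0.0365; 0.202 and 0.176 without PBS replicates 2 and 3), as 1 did when adjusted over the list alone. The list median was 0.12 (camera adjusted p = 0.178, adjusted p = 0.556 with an estimated correlation), and 0.05 without rhTR11B replicate 3. The adjusted p of SCD and DGAT2 was 0.186 for both without PBS replicate 2 and ran from 0.165 to 0.176 without PBS replicate 3. Each of PBS replicate 1, rhTR11B replicate 2 and rhTR11B replicate 3, when left out, cost 1 of the 2 calls (adjusted p up to 0.0750, 0.0524 and 0.118).

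Among 23 genes of glycolysis and hypoxia edgeR called 0, with 5 at an unadjusted p under 0.05, and DESeq2 called 1 higher and 1 lower. When adjusted over the list alone, 0 rose and 0 fell. The glucose transporter gene SLC2A1 stood at 0.31 (adjusted p = 0.0539, and 0.0430 with GC and length offsets) and PGAM1 at -0.21 (0.0685). The median was -0.02 (camera adjusted p = 0.384, adjusted p = 0.667 with an estimated correlation; median from -0.05 without PBS replicate 1 to -0.01 without PBS replicate 3). SLC2A1 passed without rhTR11B replicate 1 or 2 (adjusted p = 0.0156 and 0.0370) and had 0.18 without rhTR11B replicate 3. Among 21 genes of the unfolded protein response and ATF4 edgeR called 0, with 8 at an unadjusted p under 0.05, and DESeq2 called 2 higher and 1 lower, and adjusted over the list alone 2 rose and 2 fell. The endoplasmic reticulum chaperones HSP90B1 (0.23, adjusted p = 0.0611) and PDIA4 (0.22, 0.0811) were positive and the serine synthesis genes PSAT1 (-0.21, 0.0764) and PHGDH (-0.21, 0.0821) negative. With GC and length offsets HSP90B1, PDIA4 and PHGDH passed (adjusted p = 0.0283, 0.0485 and 0.0296). The list median was 0.04 (camera adjusted p = 0.540, adjusted p = 0.682 with an estimated correlation; median from 0.00 without rhTR11B replicate 3 to 0.11 without rhTR11B replicate 2). Without rhTR11B replicate 1 PGAM1, HSP90B1, PDIA4, PSAT1 and the NRF2 target TXNRD1 passed (adjusted p = 0.0309, 0.0480, 0.0346, 0.0242 and 0.0239), and without rhTR11B replicate 3 PDIA4 had 0.13. Of 18 NRF2 targets, 1 rose, the drug transporter gene ABCC3, from 17.0 ± 1.18 to 23.5 ± 2.41 CPM (adjusted p = 0.0117; 0.102 and 0.0749 without PBS replicates 2 and 3). When adjusted over the list alone, 1 rose and 3 fell. NQO1 had -0.09 (adjusted p = 0.344) and TXNRD1 -0.22 (0.0838). The list median was -0.07 (camera adjusted p = 0.0975, adjusted p = 0.596 with an estimated correlation; adjusted p = 0.0495 without PBS replicate 1; median from -0.10 without rhTR11B replicate 2 to -0.02 without rhTR11B replicate 3). Of 6 metallothionein list genes edgeR called 0, with 1 at an unadjusted p under 0.05 (MT1E at -0.17, adjusted p = 0.0821), and DESeq2 called 1 lower, and 1 fell when adjusted over the list alone. With GC and length offsets MT2A passed at 0.18 (adjusted p = 0.0359), against 0.04 (adjusted p = 0.725) without them. As near-identical copies these genes may exchange reads. The median was 0.01, the mean -0.01 and the test direction downward (camera adjusted p = 0.585, adjusted p = 0.682 with an estimated correlation; median from -0.05 without PBS replicate 3 to 0.04 without PBS replicate 2).

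Among 9 tested epithelial markers edgeR called 0, with 4 at an unadjusted p under 0.05, and DESeq2 called 1 higher, and 1 rose when adjusted over the list alone. The tight junction gene OCLN stood at 0.27 (adjusted p = 0.0631, and 0.0434 with GC and length offsets), the desmosomal gene DSP at 0.14 (0.127) and the keratin gene KRT8 at -0.03 (0.828). The median was 0.14 (camera adjusted p = 0.238, adjusted p = 0.434 with an estimated correlation), and 0.09 without rhTR11B replicate 3. OCLN passed without rhTR11B replicate 1 (adjusted p = 0.0317). Of 5 tested alveolar and lung lineage genes, 1 rose, the lipid transporter gene ABCA3 of alveolar type II cells, 1.21-fold (adjusted p = 0.0429), or 2 when adjusted over the list alone. The adjusted p of ABCA3 was 0.0521, 0.214 and 0.182 without PBS replicates 1, 2 and 3, and 0.0554 without rhTR11B replicate 3. The list median was 0.27 (camera adjusted p = 0.117, adjusted p = 0.442 with an estimated correlation), and 0.13 without PBS replicate 3. Few markers of other cells were high enough to test. Of the fibroblast list only COL1A1 was, with 3.07 ± 0.435 CPM with PBS and 4.73 ± 0.796 CPM with rhTR11B (adjusted p = 0.0511). Of the endothelial list only ESAM was, with 158 ± 13.2 CPM with PBS and 186 ± 17.4 CPM with rhTR11B (adjusted p = 0.0691, and 0.0341 with GC and length offsets). COL1A1 and ESAM each passed as higher by DESeq2 and when adjusted over the list alone, a list of 1 gene. COL1A1 also passed without rhTR11B replicate 3 (adjusted p = 0.0172) and ESAM without rhTR11B replicate 1 (adjusted p = 0.0359), while ESAM had 0.16 without rhTR11B replicate 3. Of 3 tested blood cell markers edgeR, also when adjusted over the list alone, and DESeq2 called 0, with 0 at an unadjusted p under 0.05, and the median was 0.27 (camera adjusted p = 0.612, adjusted p = 0.719 with an estimated correlation; median from 0.15 without rhTR11B replicate 3 to 0.39 without rhTR11B replicate 1).

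The 10 largest increases among genes with a mean of at least 2 CPM and no overlap between groups were led by CD99 (chromosome X, 2691295 to 2741309), a surface glycoprotein gene of the pseudoautosomal region, which went from 1.88 ± 0.216 to 37.5 ± 14.0 CPM (log2 fold change 4.32, SE 0.24, adjusted p = 4.98e-09). Its counts were 66, 67 and 81 with PBS and 802, 1544 and 1754 with rhTR11B. CD99 has an identical copy on chromosome Y, so its count depends on how reads that match both were treated, and its change is uncertain. The imprinted long non-coding RNA H19 (chromosome 11, 1995176 to 2001266) followed, from 1.31 ± 0.166 to 3.99 ± 1.55 CPM (log2 fold change 1.60, SE 0.25, adjusted p = 0.00409). Next were the semaphorin SEMA6B (chromosome 19, 4542593 to 4559684), from 2.30 ± 0.387 to 4.70 ± 0.514 CPM (adjusted p = 0.00561), and the ectonucleotidase ENTPD2 (chromosome 9, 137048107 to 137054061), from 1.66 ± 0.291 to 3.37 ± 0.476 CPM (adjusted p = 0.0153). The log2 fold change was 0.92 for the non-coding EOLA1-DT, 0.91 for the secreted glycoprotein gene LGALS3BP, 0.91 for the matrix gene MATN2, 0.81 for the lysosomal protease gene CTSH, 0.80 for the Toll-like receptor gene TLR6 and 0.80 for the vesicle protein gene SV2A. Their adjusted p ran from 0.0145 (CTSH) to 0.0476 (EOLA1-DT). Apart from CD99 these genes lay at 6 CPM or less in every library. Without PBS replicate 3 only CD99 of the 10 passed, H19 having an adjusted p of 0.0771, and without PBS replicate 2 only 2 passed (adjusted p up to 0.213). Of the 10, 9 passed without PBS replicate 1, and 8, 7 and 8 without rhTR11B replicates 1, 2 and 3 (adjusted p up to 0.0588, 0.0759, 0.126 and 0.0787).

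Of the 10 largest decreases by the same rule, VAMP7 (chromosome X, 155881345 to 155943769), a vesicle fusion gene that is also pseudoautosomal, went from 4.42 ± 5.34 to 0.941 ± 0.257 CPM (log2 fold change -2.23, SE 0.59, adjusted p = 0.0472). This rested on the 396 counts of PBS replicate 1, against 48 and 54 in PBS replicates 2 and 3 and 45, 31 and 27 with rhTR11B. Without PBS replicate 1 the log2 fold change was -0.50 (adjusted p = 0.363). LOC102724560 (chromosome 21, 6444869 to 6468621), a near-identical copy of the cystathionine beta-synthase gene CBS, fell (log2 fold change -0.78, SE 0.12, adjusted p = 0.00264). CBS itself had 27.1 ± 1.56 and 26.9 ± 2.04 CPM, and the sum of both genes had a log2 fold change of -0.29 (SE 0.07, adjusted p = 0.0309). The differentiation inhibitor ID4 (chromosome 6, 19837370 to 19842197) fell, from 3.55 ± 0.249 to 2.04 ± 0.380 CPM (adjusted p = 0.0305), as did ID2, from 9.71 ± 0.290 to 6.79 ± 0.872 CPM (adjusted p = 0.0249). So did the potassium channel domain gene KCTD12, from 79.7 ± 3.37 to 58.7 ± 4.50 CPM (adjusted p = 0.00264). LOC107987206, of unknown function, had a log2 fold change of -1.38, with 238 counts in PBS replicate 2 against 98 and 118 in PBS replicates 1 and 3. Without PBS replicate 2 it was -0.91 (adjusted p = 0.139). The log2 fold change was -0.66 for the dehydrogenase gene DHRS4L2, which has close copies beside it, -0.44 for the iron-sulfur cluster gene BOLA3, -0.43 for the ferredoxin gene FDX1 and -0.43 for the riboflavin kinase gene RFK. Their adjusted p ran from 0.0145 (LOC107987206) to 0.0438 (DHRS4L2). Without PBS replicate 2 or 3, LOC102724560 and KCTD12 were the only ones of the 10 to pass (adjusted p up to 0.193 and 0.179). There were 6 without PBS replicate 1, 7 without rhTR11B replicate 2 and 9 without rhTR11B replicate 3 (up to 0.363, 0.0692 and 0.0776).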

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

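The GC and length offsets, the fit to genes with a GC value and the fit without mitochondrially encoded genes were chosen after the data were seen. The 396 higher and 92 lower genes became 740 and 359 with the DESeq2 Wald test, 940 and 483 with no low-count filter, 205 and 26 at a mean of at least 5 CPM, 7 and 3 with a 2-fold change required, 62 and 16 at an unadjusted p under 0.05 with a 2-fold change, and 1056 and 556 at an adjusted p under 0.10. On FPKM values limma-trend called 62 and 21 with a pseudocount of 1, 64 and 22 with a pseudocount of 0.1, and 0 and 0 with no filter, where 3073 genes had an unadjusted p under 0.05. With 1 library left out at a time the counts ranged from 9 to 903 higher and from 3 to 427 lower, the lowest without PBS replicate 3 (9 and 3) and PBS replicate 2 (18 and 5), with 2424 and 2258 genes at an unadjusted p under 0.05 against 3279. All 488 called genes kept their direction in each of these fits, with a median log2 fold change size of 0.25 to 0.36 against 0.32. They were picked from these same libraries, and 485 of them had no overlap between groups, so their direction could hardly turn. With GC and length offsets 594 genes were higher and 192 lower, and 532 and 119 with offsets and a replicate block. That fit holds only genes with a GC value, where VAMP7, UQCRH and RPS23 did not pass without offsets (adjusted p = 0.0591, 0.0510 and 0.0501). With offsets RPS23 passed (adjusted p = 0.0415), and VAMP7 and UQCRH did not (0.0567 and 0.145). Of 137 named genes with a GC value, 70 passed without offsets, of which 2 lost the call with them and 11 others gained it. Both counts stayed within 1.5 times with DESeq2 size factors, library size alone, limma-voom, the genes with a GC value and without mitochondrial genes. Lists called by camera went from 11 to 7 with GC and length offsets, a fit that holds no mitochondrial list, to 0 with an estimated correlation (3 at an unadjusted p under 0.05), and to 1 with fry. The direction of the test turned for values that had not passed: TNFRSF11A (log2 fold change between -0.0641 and 0.0756 with 1 library left out, 0.00477 in the genes with a GC value and 0.00142 without mitochondrial genes), MT1M (-0.0389 to 0.79 with 1 library left out), MT2A (-0.0102 to 0.0796, but 0.18 with an adjusted p of 0.0359 with GC and length offsets), CORO1A (-0.22 to 0.0736), the lists of blood cell markers (median 0.15 to 0.39) and YAP/TAZ targets (-0.0519 to 0.00823, and 0.0566 in the genes with a GC value), and metallothioneins (-0.0483 to 0.0943 over all settings, the highest with GC and length offsets). The median alone changed sign for the nuclear oxidative phosphorylation list, which had passed (0.00125 with GC and length offsets), and for lists that had not: TGF-beta targets (-0.0349 to 0.107), G2/M (-0.0431 to 0.00577), p53 targets (-0.00737 to 0.0462), epithelial markers (-0.0156 to 0.168) and histones (-0.137 to 0.0126). Replicate numbers are shared between the groups. Deviations of same-numbered libraries correlated at -0.27, 0.12 and -0.03, which gave no sign of pairing but cannot exclude it with so few libraries. Only rhTR11B replicate 2 correlated best with the library of its own number (0.12). With the replicate number as a block 774 genes were higher and 252 lower, against 396 and 92 without it. Apart from the thresholds, which change the genes called by construction, the cause of these shifts was not tested. Filters change the genes tested, but calls of the same genes moved too. Among named genes tested in both fits, 28 gained a call with no low-count filter and 15 lost it at a mean of at least 5 CPM.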

Other observations

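The gene families below, the GC and length offsets, and the tests of free cytosolic RNA, of a response to rhTR11B and of pseudoautosomal genes were chosen after the data or the results they bear on had been seen. The tests of a single library and of other splits of the libraries were not, though the first was applied to these later families. Once the genes taken by the rule for largest changes and lists were set aside, the 20 further called genes with the smallest p all rose. The adhesion receptor ADGRG1 went from 14.8 ± 0.926 to 23.7 ± 1.09 CPM (log2 fold change 0.68, SE 0.08, edgeR adjusted p = 9.10e-04), complement C3 (chromosome 19, 6677704 to 6720650) from 113 ± 13.9 to 195 ± 34.6 CPM (adjusted p = 0.00115) and the anchoring fibril collagen COL7A1 (chromosome 3, 48564073 to 48595329) from 91.6 ± 12.8 to 142 ± 11.7 CPM (adjusted p = 0.00115). The log2 fold change was 0.67 for SECTM1, 0.68 for the sialomucin gene PODXL, 0.58 for the integrin ligand gene NPNT, 0.46 for TBC1D8, 0.62 for the adhesion gene L1CAM, 0.61 for the secreted chaperone gene CLU, 0.48 for the endocytic receptor gene LRP1 and 0.55 for TLR2. COL6A1 and COL6A2 rose by 0.55 and 0.40, TINAGL1 by 0.51, LRRN4 by 0.45, the endothelin-converting enzyme ECE1 by 0.40, AASS by 0.40, GPRC5B by 0.38 and the mitochondrial iron carrier SLC25A37 by 0.38. Without PBS replicate 3, 8 of these 20 passed and the adjusted p of the 20 ran from 0.0245 to 0.115, and without PBS replicate 2, 13 passed.

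By gene family, 7 of 16 collagen genes rose (median log2 fold change 0.35), 5 of 8 laminin chains (0.31), 6 of 22 integrin chains (0.23), 5 of 11 cathepsins, lysosomal proteases (0.29), and 8 of 22 semaphorins and plexins (0.32). With camera's preset correlation their adjusted p was 5.79e-11, 1.40e-07, 5.41e-05, 6.37e-08 and 2.16e-09, and with an estimated correlation the adjusted p was 0.236, 0.236, 0.241, 0.236 and 0.241. Of 18 small membrane proteins of the SMIM family, 2 fell and the median was -0.07 (adjusted p = 0.0155, and adjusted p = 0.236 with an estimated correlation). Of the 434 tested ZNF genes 1 fell, and they had a median of 0.01 (adjusted p = 0.633). Of 163 TMEM genes 6 rose (0.14), and of 165 SLC transporter genes outside SLC25 10 rose (0.18). The median was -0.15 for 38 proteasome subunits, -0.14 for 51 initiation factors and -0.14 for 77 mitochondrial ribosomal proteins, of which 2 fell. Among proteasome subunits and initiation factors edgeR called 0, with 24 and 27 at an unadjusted p under 0.05, and DESeq2 called 5 and 9 lower. The camera adjusted p of these 5 families was 1.94e-07, 8.88e-13, 1.72e-09, 1.98e-09 and 2.85e-12. It was adjusted p = 0.266, 0.246, 0.246, 0.241 and 0.241 with an estimated correlation. Apart from the TMEM, SLC and ZNF genes, these families were not tested with GC and length offsets.

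For the higher level of TMEM and SLC genes, GC content and transcript length are argued against as the whole cause. Offsets for both left the joint TMEM and SLC median, relative to tested genes with a GC value, at 0.15 (95% bootstrap interval over genes 0.14 to 0.18). That is a ratio of 0.938 to the 0.165 of the same genes without offsets. As the only source, rhTR11B replicate 3 is also argued against, but only weakly. Without it the relative median was 0.0858 (interval 0.07 to 0.11) against 0.161 with all libraries, a gap that this library did widen. Set against the PBS mean, TMEM medians were 0.08, 0.07 and 0.28 in rhTR11B replicates 1 to 3 and 0.03, -0.05 and 0.01 in PBS replicates 1 to 3. Those of SLC genes were 0.10, 0.10 and 0.30, and 0.04, -0.04 and -0.002. In both families rhTR11B replicates 1 and 2 exceeded the highest PBS library by less than the PBS libraries differed among themselves. The intervals resample genes, which are not independent, and leave out the spread between libraries. A lower yield of free cytosolic RNA relative to membrane-bound RNA may contribute: the 41 SLC25 carriers, membrane proteins made on free ribosomes, had a median of -0.05, which is -0.23 when the median of the other SLC genes is subtracted (permutation p = 1e-05 across genes, which are not independent; the smallest that 100000 permutations can give), and 12 nuclear-retained RNAs and 13 mitochondrially encoded genes had medians of 0.19 and 0.33. Those last medians had in part been seen beforehand, and not every family follows this account, since the ZNF genes, whose proteins are made on free ribosomes, had a median of 0.01 and the SMIM membrane proteins -0.07. The SLC25 contrast also cannot tell RNA yield from a lower level of nuclear genes for mitochondrial proteins. Medians were -0.14 for mitochondrial ribosomal proteins and -0.09 for nuclear oxidative phosphorylation genes (0.00 with GC and length offsets). A response of the cells to rhTR11B, as the source of the relative median of 0.161, stays open and was not tested apart from handling, since no library was handled as the treated cultures were without rhTR11B.

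Counts of pseudoautosomal genes jumped between libraries: besides CD99 and VAMP7, SLC25A6 had 1221 counts in rhTR11B replicate 1 and 132 to 180 in the other 5 libraries. Because these 3 genes prompted the test, it was run on the other 6 tested pseudoautosomal genes. Their median dispersion lay at percentile 94.4 of 10000 random lists matched on mean expression, and the median ratio of the highest to the lowest library within groups was 2.07 against 1.56 in matched lists, at percentile 99.5. These values straddle the bound of 95 that was set, so reads shared between the X and Y copies stay open as the source of the spread. Whether CD99, at a log2 fold change of 4.32, also responded to rhTR11B cannot be told apart from this, while its 3 rhTR11B libraries all lay higher.

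Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split gave 396 higher genes and the highest other split 0 by edgeR (up to 1262 genes at an unadjusted p under 0.05), so 1 of the 10 gave as many. For lower genes the real split gave 92 and the highest other split 1, so again 1 of the 10 gave as many. For lists called by camera 2 of the 10 gave as many, 11 in the real split and 12 in the split that set PBS replicate 1 and rhTR11B replicates 1 and 3 against the rest. The mitochondrial share of counts in those 3 libraries was 7.71%, 8.75% and 10.4%, against 6.63%, 7.31% and 7.88% in the other 3.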
